A study of Schmidtea mediterranea with 6 samples.

How the data were processed

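RNA was measured by sequencing in whole bodies of the planarian flatworm Schmidtea mediterranea. The series holds 6 libraries in 2 groups of 3: animals without treatment, labelled day 0, and animals labelled day 3 after a lethal dose of irradiation. Per the labels' protocols, total RNA was extracted with TRIGene reagent and made into Illumina libraries with a NEBNext kit. The authors deposited a table of estimated counts per gene ID, of which most values are whole numbers and 7.71% to 9.34% per library are not, at a tolerance of 1e-06. Estimated counts that are not whole can arise where reads are divided between genes, and such genes are reported as uncertain. The authors also deposited a table of TPM, which are scaled for gene length and sum to the same total in each library, for the same 36035 gene IDs. The aligner, the counting program, the transcript set, the genome build and the strand setting are not given in the sources used here. Column headings matched the description label of exactly one sample each, and no column belonged to another sample.

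The library totals lay between 12635699 and 20914353 estimated counts. At these totals, 3 counts over the whole irradiated group correspond to 0.0671 CPM (counts scaled to library total), which was used as the detection floor for genes without a count in that group. Counting intervals are exact 95% Poisson intervals and cover counting error only, since reads amplified without molecular identifiers are not independent molecules. The smallest exact two-sided permutation p for 3 libraries against 3 is 0.1, so single library measures could not pass 0.05.

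Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 under R 4.3.3. Genes with low counts were removed with edgeR's default expression filter, which works from a minimum count of 10. Libraries were scaled with TMM factors, and irradiated libraries were compared with unirradiated libraries by the quasi-likelihood F test with no covariate. CPM values were scaled by the library total over the tested genes times the TMM factor. The detection floor, and the level of genes without a count after irradiation, used plain library totals instead. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The sources used here do not state the test the authors used. Standard errors of log2 differences come from the spread of log2 CPM (prior count 2) between the libraries of each group. They are not the errors of the edgeR estimates, and the prior count narrows them where counts are few. TPM values were used for the shares of the transcript pool and, on a log2 scale, for alternative tests with limma 3.58.1.

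The procedure was tested on simulated counts for this comparison. They were drawn from the means of the unirradiated libraries and from the library sizes and dispersions of all real libraries. A change was given to 200 genes, and 19882 genes passed the expression filter after simulation and were tested. The procedure recovered 100% of the tested genes lowered by 3 on the log2 scale, 75.7% of those lowered by 1 and 48.7% of those lowered by 0.5. Of the genes raised, 87.2% were recovered at 1 and 60.5% at 0.5. Of the unchanged genes, 0.102% were called, which was 20 of 19692. Recovered genes numbered 37, 28 and 19 for falls of 3, 1 and 0.5, and 34 and 23 for rises of 1 and 0.5. The share of false calls among all simulated calls was thus above the threshold set for adjusted p. The simulation changed 200 genes, whereas 7191 were called in the real data. It therefore did not test the scaling of libraries with that many changes.

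The design, the alternatives and the rule for named genes were fixed before the data were examined. The alternatives were other scalings (RLE, upper quartile, library size), a weaker and a stricter filter, DESeq2 1.42.0, limma-voom, 3 limma tests on TPM with pseudocounts of 1 and 0.1, the replicate number as a block, and leaving out each library. A fit to genes with whole-number counts and a TMM scaling over the genes not called lower were added after seeing the data. A total of 20 gene lists (stem cell, replication, mitosis, tissue and stress genes among them) had also been fixed by gene name. The files do not pair their IDs with gene names and no annotation was used here, so 0 of the 36035 IDs matched a list, and no list was tested. The rule for that case named the 2 IDs higher and the 2 lower with the smallest p.

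Replicate numbers 1 to 3 occur in both groups, and no source states that they mark shared animals or days. Replicates were also checked for duplicate libraries. Chi-square per degree of freedom, over genes with a summed count of at least 10, ran from 2.55 to 5.26 for pairs within a group, so no pair of libraries agreed within sampling noise. No label says that the replicates came from separate animals or cultures, and p-values then measure the spread between these libraries, which may be technical.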

Results

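Whole-body transcript levels of Schmidtea mediterranea were measured 3 days after lethal irradiation and in unirradiated animals. This freshwater flatworm regenerates from proliferating stem cells called neoblasts, which are known to be eliminated by lethal irradiation. Each group had 3 libraries. The unirradiated libraries held 13030427, 12963851 and 20914353 estimated counts, and the irradiated libraries held 12714020, 12635699 and 19329424. Totals did not differ between the groups by more than their spread (n = 3; exact permutation test, two-sided, p = 0.5, adjusted 0.5 over 5 library measures). The deepest library of each group carried replicate number 3, so depth was spread alike over the groups.

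Libraries separated by treatment. The first principal component of log2 CPM carried 69.7% of the variance and placed all 6 libraries on the side of their group, and the second carried 9.51%. Across genes, which are not independent replicates, Pearson's r lay between 0.986 and 0.989 for libraries of one group and between 0.950 and 0.955 for libraries of different groups. Thinned to the smallest library total, 29895 ± 170 gene IDs had a count in unirradiated animals and 29228 ± 74 in irradiated animals (SD, n = 3). The ranges did not overlap, and the exact two-sided permutation p was 0.1, the smallest this design allows (adjusted 0.25 over 5 library measures). Without thinning the numbers were 30266 ± 643 and 29537 ± 504, with an exact permutation p of 0.3 (n = 3).

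The comparison that the series describes is between animals 3 days after lethal irradiation and untreated controls. A total of 4154 genes were lower and 3037 were higher in irradiated animals among 20378 tested. The falls reached far larger sizes than the rises. At least a 2-fold change was seen for 1100 of the genes that fell and for 92 of those that rose. Of the genes that fell, 210 were at least 8-fold lower, while 1 gene rose at least 4-fold. The median log2 fold change was -0.65 for the genes that fell and 0.41 for the genes that rose, and 80.3% of the rises were under 1.5-fold. The counts of large changes depended on the low-count filter and, on TPM values, on the pseudocount. The 210 became 433 without a filter and 120 with at least 50 counts in 3 libraries. With other tests on the same counts they were 212 (DESeq2) and 216 (limma-voom), and with limma on log2 TPM they were 185 with a pseudocount of 0.1 and 48 with a pseudocount of 1. The 1100 lay between 659 and 1424 over all settings. The 92 lay between 27 and 179. All calls are at an adjusted p below 0.05 in edgeR's quasi-likelihood test. The 3 libraries of one group did not overlap the 3 of the other for 6967 of the 7191 genes called. Over all genes tested, 45.6% had groups that did not overlap, against 10% from chance.

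**Figure D1:**
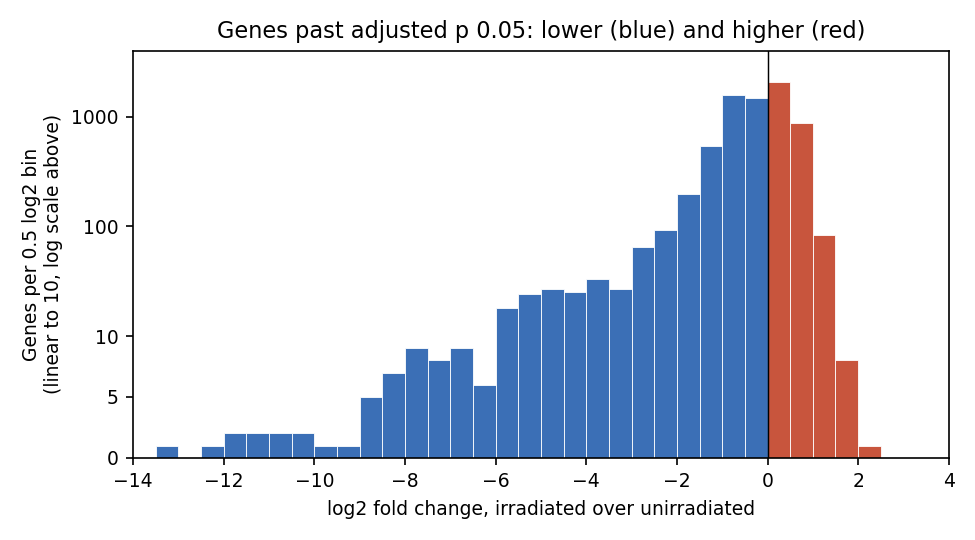
Number of genes past an adjusted p of 0.05 (vertical axis, linear to 10 and logarithmic above) per 0.5-wide bin of log2 fold change of irradiated over unirradiated libraries (horizontal axis); blue bars are lower genes and red bars higher genes. The blue bars extend far to the left, with 210 genes lower by at least 8-fold (48 to 433 over other settings), whereas 92 genes were higher by at least 2-fold.

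The division of calls between falls and rises depended on the scaling of libraries. With TMM, 42.2% of calls were rises. With upper-quartile scaling 4191 genes were higher and 3593 lower, so that 53.8% of calls were rises, and the median log2 fold change of all genes tested moved from 0.01 to 0.08. With TMM factors from the genes not called lower, a setting added after seeing the data, 1698 genes were higher and 5285 lower, so that 24.3% of calls were rises. This setting drops only genes that fell and keeps those that rose, so the direction of its move was built in. Falls of at least 2-fold outnumbered rises of that size under both settings, but the size of the excess moved: 985 genes against 152 with upper-quartile scaling, and 1331 against 48 with factors from the genes not called lower. Irradiation and sampling time could not be told apart, because the untreated animals were labelled day 0 and the irradiated animals day 3.

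Among the genes that fell, SMED30014876 and SMED30007406 had the smallest p-values. SMED30014876 fell from 1079 ± 22 CPM to 0.69 ± 0.28 CPM (SD, n = 3), a log2 fold change of -10.70 with a standard error of 0.30 and an adjusted p of 2.08e-17 in edgeR. It held between 13477 and 22626 counts in unirradiated libraries and between 8 and 12 in irradiated libraries. At counts this low, the prior count narrows the standard error given. Its estimated count was whole in 3 of the 6 libraries, as happens where reads are divided between genes, and its level is uncertain to that degree. SMED30007406 fell from 390.5 ± 2.5 CPM to 7.08 ± 0.60 CPM (SD, n = 3), a log2 fold change of -5.79 with a standard error of 0.07 and an adjusted p of 8.32e-17 in edgeR. This gene kept 1.81% of its unirradiated level, whereas SMED30014876 kept 0.064%. The files do not pair these IDs with gene names.

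Among the genes that rose, SMED30003962 and SMED30017762 had the smallest p-values. SMED30003962 rose from 164 ± 16 CPM to 382 ± 21 CPM (SD, n = 3), a log2 fold change of 1.22 with a standard error of 0.09 and an adjusted p of 3.44e-09 in edgeR. Its estimated counts were whole in 0 of 6 libraries, so its level is uncertain in the same way. SMED30017762 rose from 47.9 ± 4.2 CPM to 100.3 ± 5.2 CPM (SD, n = 3), a log2 fold change of 1.06 with a standard error of 0.09 and an adjusted p of 1.47e-08 in edgeR. In both, every irradiated library lay above every unirradiated library.

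**Figure D2:**
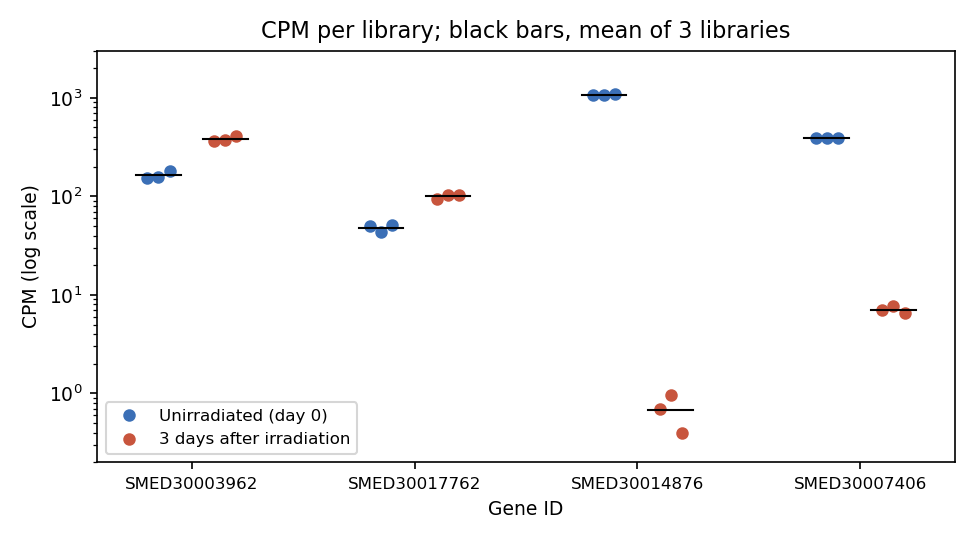
CPM on a log axis for 4 gene IDs (horizontal axis) in each unirradiated library (blue) and each library 3 days after irradiation (red); black bars are means of 3 libraries. SMED30014876 lay at 1079 CPM unirradiated and 0.69 CPM irradiated, while SMED30003962 lay at 164 and 382 CPM.

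The genes that fell most contributed a small part of the transcript pool. The 210 genes at least 8-fold lower made up 1.05 ± 0.02% of all TPM in unirradiated animals and 0.023 ± 0.001% in irradiated animals (SD, n = 3). The 158 genes lower by 4-fold to 8-fold went from 0.180 ± 0.010% to 0.039 ± 0.003%, and the 732 genes lower by 2-fold to 4-fold from 3.78 ± 0.14% to 1.59 ± 0.16%. The largest loss of pool share came from the 3054 genes that fell by less than 2-fold, which went from 32.3 ± 0.6% to 24.2 ± 0.1%. The 2945 genes that rose by less than 2-fold went from 25.9 ± 0.1% to 35.4 ± 0.7%. The 92 genes at least 2-fold higher took 0.076 ± 0.003% before and 0.176 ± 0.007% after. The class of 210 genes held 48 to 433 genes under other settings. The classes were formed from the same libraries, so their shares describe the calls and are not independent evidence of direction. Restricted to genes whose estimated counts were whole in all libraries, the genes at least 8-fold lower held 0.481% of TPM in unirradiated animals instead of 1.05%.

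**Figure D3:**
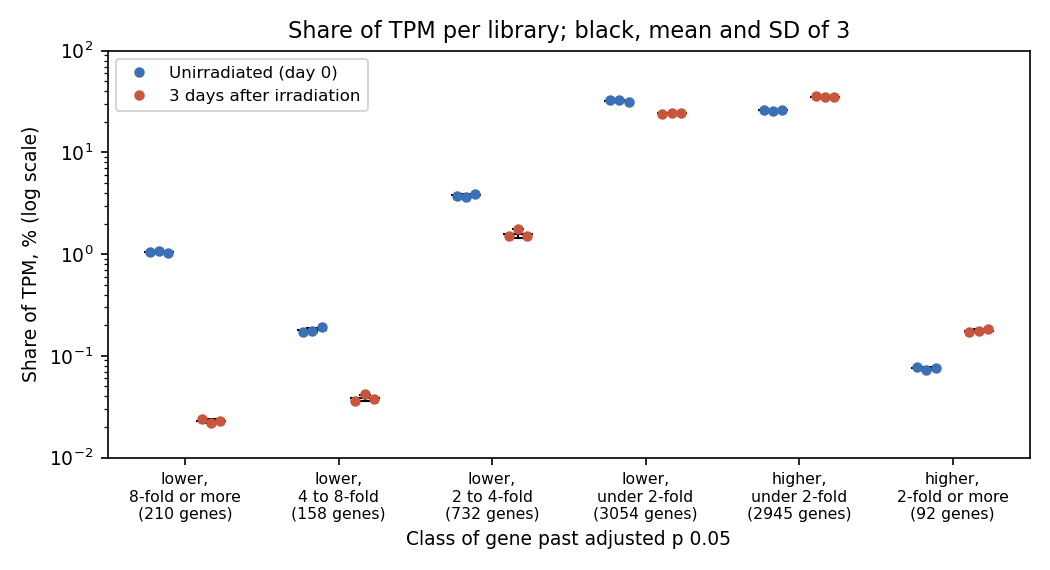
Share of TPM in percent (log axis) held by 6 classes of genes past an adjusted p of 0.05 (horizontal axis) in each unirradiated (blue) and irradiated (red) library; black marks give the mean and SD of 3 libraries. The class at least 8-fold lower went from 1.05% to 0.023%, and the class higher by under 2-fold from 25.9% to 35.4%.

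Falls and rises of at least 2-fold were found at every level of abundance, in classes formed by the mean CPM over all 6 libraries, which a change itself moves. Among 1683 genes with a mean of 100 CPM or more, 443 fell and 480 rose, and 48 fell by at least 2-fold against 1 that rose as much. Among 5397 genes of 20 to 100 CPM, 1492 fell and 1302 rose, with 153 and 6 of them changed at least 2-fold. Among 5486 genes of 5 to 20 CPM, 1406 fell and 934 rose, with 325 and 15 changed at least 2-fold. Among 6282 genes of 1 to 5 CPM, 686 fell and 304 rose, with 447 and 53 changed at least 2-fold. Below 1 CPM, 127 of 1530 genes fell and 17 rose, and each of these calls was at least 2-fold.

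The 100 most abundant genes changed moderately. Of these, 46 rose, 13 fell and 41 did not pass the threshold, and their log2 fold changes lay between -0.75 and 0.64. The most abundant gene took 5.04 ± 0.50% of all counts in unirradiated animals and 4.15 ± 0.16% in irradiated animals (SD, n = 3), and its log2 fold change was -0.32 with an adjusted p of 2.66e-04 in edgeR. The 10 most abundant genes of each library together took 12.7 ± 0.4% and 12.1 ± 0.2% of the counts (exact permutation test, two-sided, p = 0.2, adjusted 0.333, n = 3).

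Some transcripts fell below detection after irradiation, and no gene appeared from below detection. Of 19223 genes with at least 10 counts in every unirradiated library, 79 had 3 or fewer counts over all irradiated libraries and 24 had none. The most abundant of those 24 averaged 36.0 CPM in unirradiated animals and was at least 536-fold lower after irradiation, taking 3 counts over the irradiated group as the floor. Of 18721 genes with at least 10 counts in every irradiated library, 0 had 3 or fewer counts over all unirradiated libraries.

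The strongly reduced genes did not fall to one common level. Of 59 genes with at least 10 CPM in unirradiated animals that were at least 8-fold lower, 25 kept under 1% of the unirradiated level, 17 kept 1% to 5% and 17 kept more than 5%. Among the 13 of at least 100 CPM, the level left ranged from 0.0091% to 12.1% with a median of 0.213%. For 9 of these 13 the upper counting limit (exact Poisson, 95%) lay below 1%, and for the other 4 the lower limit lay above 1%.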

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

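The fit to genes with whole-number counts and the scaling over genes not called lower were chosen after seeing the data; the other settings were planned. Of the planned settings, unfiltered limma on log2(TPM + 1) kept the fewest main calls, 69.8% of the higher and 64.7% of the lower. No main call was reversed under any of the 19 settings (0 genes). The 4 named genes kept their direction and an adjusted p below 0.05 wherever tested. All settings reuse these libraries, from which the 4 genes were chosen for the smallest p, so both outcomes were close to built in. SMED30014876 ranged from -10.99 to -9.62 and SMED30007406 from -5.90 to -5.19 on the log2 scale. SMED30003962 ranged from 1.11 to 1.31 and SMED30017762 from 0.96 to 1.15. The number of genes lower stayed within 1.5 times of 4154 in all 19 settings, from 2956 to 5285. The number higher did so in 18, and fell from 3037 to 1698 with TMM over the genes not called lower, which moved the median log2 fold change by -0.11 and left 24.3% of calls as rises. That setting drops only genes that fell, so this direction was built in. The 92 genes at least 2-fold higher became 152 with upper-quartile scaling, 179 without a low-count filter, 27 with at least 50 counts in 3 libraries and 48 with TMM over the genes not called lower. Leaving out one library gave 109 to 154 such genes, the highest without unirradiated replicate 1, and 1070 to 1151 genes at least 2-fold lower. The 1100 genes at least 2-fold lower became 686 with at least 50 counts in 3 libraries, 659 with limma on log2(TPM + 1) and 688 with the latter unfiltered. The 210 genes at least 8-fold lower became 433 without a filter, 120 with the stricter filter, and 48 with limma on log2(TPM + 1), filtered or not, where the pseudocount understates changes of scarce genes. The filters differ in the genes they test (33483 without one, 14150 with the stricter one, 20378 in the main comparison); the other causes were not tested. The replicate number as a block gave 2856 genes higher and 4061 lower. No pairing by number was seen: deviations of equal numbers correlated at -0.04, 0.07 and -0.07, and 1 of 6 libraries correlated best with its own number. With 3 libraries per group this check cannot exclude pairing, and the deepest library of each group carried number 3. Gene lists were not tested, since no gene ID matched one. Recovery was lower for scarce genes. Of simulated changes of 1 on the log2 scale, 45.8% were recovered below 5 CPM (24 genes) and 98.1% above (52 genes). Depth was not varied.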

Other observations

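Tests of library scaling, of shared reads on the ratio of large changes, of the relative share of rises and of other splits came first. They were stated before their own results were seen. The tests of shared reads and relative share, and part of the scaling test, used settings added after seeing the data. The remaining tests were chosen after results had been seen. All 9 other splits of the 6 libraries into 3 and 3 called fewer genes than the real one, so that 1 of 10 splits reached the real count. The real split called 7191 genes in edgeR and the highest of the others 0, with 200 to 497 genes at an unadjusted p below 0.05 and at most 3 calls in DESeq2 against 6110 for the real split. Each of the 9 other splits mixes treated and untreated libraries on both sides, so the treatment difference widens the spread within each side. Few calls were therefore built in, and these splits do not measure how many calls chance alone would give. With 10 splits, no share under 0.05 is possible.

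Genes that fell at least 2-fold outnumbered those that rose as much by 1100 to 92. Library scaling moved the size of this excess, and the lowest ratio over 4 other scalings was 6.48. These scalings placed the median log2 fold change of all genes between -0.09 and 0.08. With limma on log2(TPM + 0.1) the ratio was 6.40. Shifts of the median this small could hardly have removed an excess this large. The scaling over genes not called lower could only raise it. These values show only that scaling differences of that size did not remove the excess. A larger change in total RNA per animal does not show in relative counts and was not tested. Neither shared reads nor gene length accounted for the excess as the whole cause. The ratio was 12.4 among genes with whole-number counts in all libraries. Genes were also split into 3 equal classes by effective length, taken from the ratio of count to TPM. The ratio of falls to rises went from 7.16 in the shortest class to 14.3 and 32.7. Its size thus went with length, while large falls prevailed in each class. From the shortest to the longest class, large rises numbered 56, 26 and 10, and large falls 401, 372 and 327. Over all genes, the Spearman correlation of effective length with log2 fold change was 0.002. Low counts did not account for the excess either, with a ratio of 28.7 among genes of at least 20 CPM (201 lower, 7 higher). A candidate explanation that stays open is the loss of radiation-sensitive cells with their transcripts, as against lower transcript levels within cells; whole-body libraries without gene names do not separate these, and the 3 days between the groups also stay open as an untested factor.

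The strongly reduced genes of at least 100 CPM kept 0.0091% to 12.1% of their unirradiated level. Reads carried over from unirradiated libraries would leave every gene the same share, and the third-lowest upper limit of 0.077% puts such carry-over far below the 4 genes with more than 1% left. One equal share of surviving expressing cells as the only source of what is left is argued against. The chi-square per degree of freedom for an equal share was 1275 over the 13 genes, set against counting error only. It does not test equal survival together with unequal expression in surviving cells or unequal transcript decay. Reads shared with near-identical genes did not account for the spread: among the 8 genes with whole-number counts, 4 had an upper counting limit below 1% and 4 a lower limit above 1%, and the highest level left was 239 times the upper limit of the lowest. The choice of genes at least 8-fold lower bounds the level left from above, so the upper end of this range is set by that choice. It may be that these genes differ in how far cells that survive irradiation also express them, or in how fast their transcripts decay; neither was tested.

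The 3037 rises were mostly under 1.5-fold, a size at which a loss of other transcripts could by itself raise the relative share of the rest. With scaling factors taken from genes not called lower, 1698 of these calls remained, and the median log2 fold change of all 3037 went from 0.41 (interquartile range 0.24) to 0.31 (0.24). For the 1339 whose call ended, the median went from 0.29 to 0.19. This follows from the median shift of -0.11 over all genes and does not by itself show whether these genes rose. Since these genes were chosen for being higher, the same choice was repeated on 2 libraries per group, and the fold was measured in the 2 libraries left out. Over the 9 choices, such genes had a median log2 fold change of 0.15 to 0.26 in the libraries left out. Genes not called had -0.05 to -0.03. The choices share libraries, so they are not independent checks, and each fold came from a single library per group. Within that limit, the values argue against an equal rise of every transcript that was not lost as the whole cause. Unequal rises from a change in the proportions of cell types stay open and were not tested.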
